A study of Homo sapiens with 6 samples.

How the data were processed

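RNA was sequenced from cells labelled AGS, a human gastric adenocarcinoma line, harvested 48 h after transfection with a control plasmid or with a plasmid that carries IGF2BP3. Each group had 3 libraries. Per the labels' protocols, 1 μg of total RNA per sample was treated with DNase, polyadenylated RNA was captured on beads, a strand-marking kit was used, products of 300 to 500 bp were kept and 150 nt paired-end reads were taken on an Illumina instrument. Per the submitters' processing notes, HISAT2, DESeq2 and the genome build GRCh38 were used, without versions. The gene counter, its strand setting and its annotation release are not given in the sources used here, so an antisense gene and its partner, overlapping genes and near-identical copies may share reads and are uncertain where they are named.

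The authors deposited raw read counts per gene, whole numbers for 32943 genes with at least 1 read in total, and FPKM for 32477 genes rounded to 2 decimals. A gene's deposited counts divided by the authors' FPKM gave the relative totals behind the FPKM. They did not follow the sums of the gene counts. Relative to control plasmid replicate 1, the gene counts' share of that total was 1.04 and 1.05 times as large in the other controls. With overexpression it was 1.06 to 1.07 times as large, so the groups did not overlap (exact permutation p = 0.1, the smallest possible). FPKM were therefore used only as an alternative. Library totals were 33555366 to 37633587 counts.

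The libraries were grouped by their titles. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No 2 libraries agreed within sampling noise: over the genes tested, chi-square per gene was 2.04 or more for every pair. It was 2.04 between control replicates 2 and 3 but 9.30 and 8.74 for control replicate 1 against them, and 2.48 between overexpression replicates 1 and 2 but 7.58 and 7.99 for overexpression replicate 3.

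Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults, a minimum count of 10 and a minimum total of 15, which left 17747 genes. Libraries were scaled by TMM, and the quasi-likelihood F test compared the groups with no other term in the model. Benjamini-Hochberg adjusted p under 0.05 was the threshold, with no fold limit. Fold changes are overexpression over control. Levels are CPM, edgeR's counts scaled to TMM-adjusted library sizes, and the ± after a level is the SD over 3 libraries. Standard errors of log2 fold changes were taken from the fold change and the F statistic. IGF2BP3 was also tested by a two-sided exact permutation test.

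Before the data were examined, 40 gene lists were written from general knowledge, and 39 with at least 3 tested members were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 3. Camera compares a list with all other genes, here with a preset inter-gene correlation of 0.01. Endothelial markers, with 2 tested members, were not tested. Camera with a correlation estimated per list and fry, which asks whether a list's genes move one way on balance, were alternatives. Of the tested genes in these lists, 52 were in more than 1 list. A further 6 lists used in the closing section were written after the genes with the largest changes had been seen.

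The genes named were set by a rule fixed before the data were examined. It took the 3 IGF2BP genes. It took the 8 highest and 8 lowest log2 fold changes among genes past the threshold that had a symbol, no overlap between the groups and at least 5 CPM in the higher group. It took the 4 genes with the largest rise and the 4 with the largest fall in CPM. It took the 4 members with the smallest p in the direction of each list past camera's threshold, and the 2 with the smallest p of each other list. Other genes are named as chosen after their values were seen. Some genes that the rule took are not reported here.

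The alternatives fixed before the data were examined were other scalings, other filters, the replicate number as a block, each library left out, the scaling without IGF2BP3 and mitochondrial genes, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with pseudocounts of 1 and 0.1, fold limits of 1.5 and 2 and an adjusted p under 0.01. Added after seeing the data was the comparison of long noncoding and protein-coding genes on each side of a mean of 10 CPM. So were the removal of a trend on GC content and transcript length and a test against a fold of 1.5 (edgeR glmTreat). Leaving out control replicate 1 and overexpression replicate 3 together was also added then. GC content and length came from the longest transcript of each gene in GENCODE release 29 (GRCh38), matched on the Ensembl ID without its version for 98.6% of the genes tested, and splines with 5 degrees of freedom were removed per library. Positions of genes are from the same annotation.

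The pipeline was tested on simulated counts for this comparison, drawn from the real means and library sizes with 200 changed genes, of which 50 had each fold. Of 17506 genes tested there, the share of changed genes recovered was 26% at a fold of 1.2, 68% at 1.5, 86% at 2 and 94% at 4, and 6 unchanged genes were called. With a simulated rise of 1.2-fold in the 36 MYC targets, camera called that list and 0 of the other 38 lists. Counts were drawn independently for each gene, so this could not test the preset inter-gene correlation of camera. The simulated changes were few and evenly split between rises and falls. The real comparison called 6698 genes, with 1268 falls and 406 rises at a fold of 1.5 or more. The recovered shares therefore do not carry over to it, and TMM under uneven changes was not tested. Spread followed edgeR's fitted dispersion alone, so outlying libraries were not simulated. A simulated GC trend gave 6937 calls without the correction and 0 with it. That trend was built from the same GC values that the correction uses, so other forms of bias were not tested. Alternative splicing, which the series also concerns, was not analysed here, since only values per gene were used.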

Results

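IGF2BP3 is an RNA-binding protein of the insulin-like growth factor 2 mRNA-binding family, which is known to bind mRNAs, including m6A-modified ones, and to affect their stability and translation. The series asked which genes lie downstream of IGF2BP3 in cells labelled AGS, a gastric adenocarcinoma line. Expression was measured by polyA RNA sequencing in 3 libraries with a control plasmid and 3 libraries with IGF2BP3 overexpression, 48 h after transfection. The control libraries held 35526144, 33555366 and 36264366 counts and the overexpression libraries 37633587, 35731829 and 36668695. The first principal component, with 59.1% of the variance, separated the groups. On it overexpression replicate 3 (35.8 against 20.3 and 23.4) and control replicate 1 (−35.3 against −21.4 and −22.8) lay farthest out in their groups. The second component, with 13.02%, set control replicate 1 apart from the other controls. In that library the signal recognition particle RNA RN7SL1, which has near-identical copies and is uncertain, was at 331 CPM against 63.3 and 57.0 CPM in the other controls.

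IGF2BP3 (ENSG00000136231.14; GRCh38 chromosome 7, 23310209 to 23470467, minus strand, protein-coding) was higher in each overexpression library than in each control library. It was at 90.6, 102 and 100.2 CPM in the control libraries and at 511, 573 and 664 CPM in the overexpression libraries. The means were 97.6 ± 6.22 and 583 ± 76.9 CPM (SD, n = 3 each), a 5.97-fold difference with a log2 fold change of 2.58 ± 0.08 (SE). It had the smallest p of all genes tested (edgeR quasi-likelihood adjusted p = 1.278e-08). The exact permutation test gave p = 0.1, two-sided, the smallest that 3 against 3 libraries allow. The authors' FPKM rose from a mean of 9.54 to 59.0. Counts per gene do not separate transcripts of the plasmid from those of the cell's own gene. The related IGF2BP1 was at 206 ± 0.451 and 215 ± 7.37 CPM (log2 fold change 0.06 ± 0.04, adjusted p = 0.27), and IGF2BP2 at 31.3 ± 1.48 and 31.0 ± 1.23 CPM (log2 fold change −0.02 ± 0.06, adjusted p = 0.86). Neither passed the threshold, and the family as a list did not pass either (1 of 3 higher, camera adjusted p = 0.19).

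**Figure D1:**
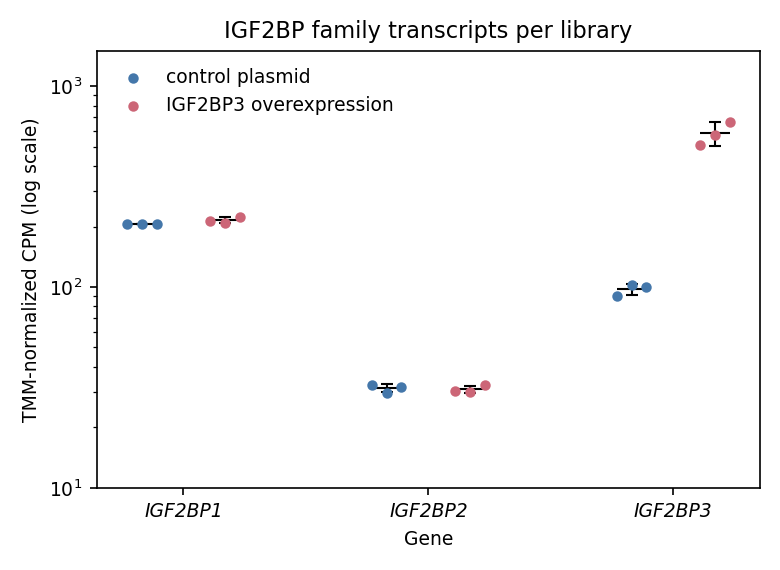
TMM-normalized CPM (log axis) of the 3 IGF2BP genes. Each point is a library, bars are the mean ± SD of 3 libraries, and IGF2BP3 lies at 90.6 to 102 CPM in control libraries and 511 to 664 CPM in overexpression libraries.

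Of 17747 genes tested, 6698 differed between the groups (edgeR adjusted p under 0.05), 3288 higher and 3410 lower with IGF2BP3 overexpression. Most changes were small, with a median absolute log2 fold change of 0.37 among the genes called. At a fold of 1.5 or more there were 406 rises and 1268 falls, and at a fold of 2 or more 84 rises and 512 falls. Among the genes called, the share of falls was larger at low levels, 70.7% of 1835 genes under a mean of 10 CPM and 43.5% of 4863 genes at 10 CPM or more. Of 2975 long noncoding RNAs tested 409 fell and 154 rose, and of 13869 protein-coding genes 2922 fell and 3091 rose. On each side of a mean of 10 CPM the shares of falls among genes called lay closer. Under 10 CPM they were 77.0% of long noncoding RNAs and 68.6% of protein-coding genes (Fisher's exact test, odds ratio 1.54, p = 7.374e-04). At 10 CPM or more they were 55.7% and 43.1% (odds ratio 1.66, Fisher's exact p = 0.0076). These tests are across genes, which are not independent. Levels were not matched within either side, so a difference at equal level was not tested. Long noncoding RNAs took 1.525 ± 0.085% of counts in controls, with 1.62% in control replicate 1, and 1.516 ± 0.012% with overexpression. Their falls were not recounted without control replicate 1. The groups did not overlap for 8988 genes, 50.6% of those tested, where chance gives 10%. Tested against a fold of 1.5 itself, 367 genes were called, 53 higher and 314 lower. With limma on log2 of the authors' FPKM plus 1, over 17746 genes, the split turned to 3416 higher and 2453 lower. For the 11474 genes with a mean FPKM of at least 1 it was 3391 higher and 1922 lower, where the filter also removed genes of low level.

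**Figure D2:**
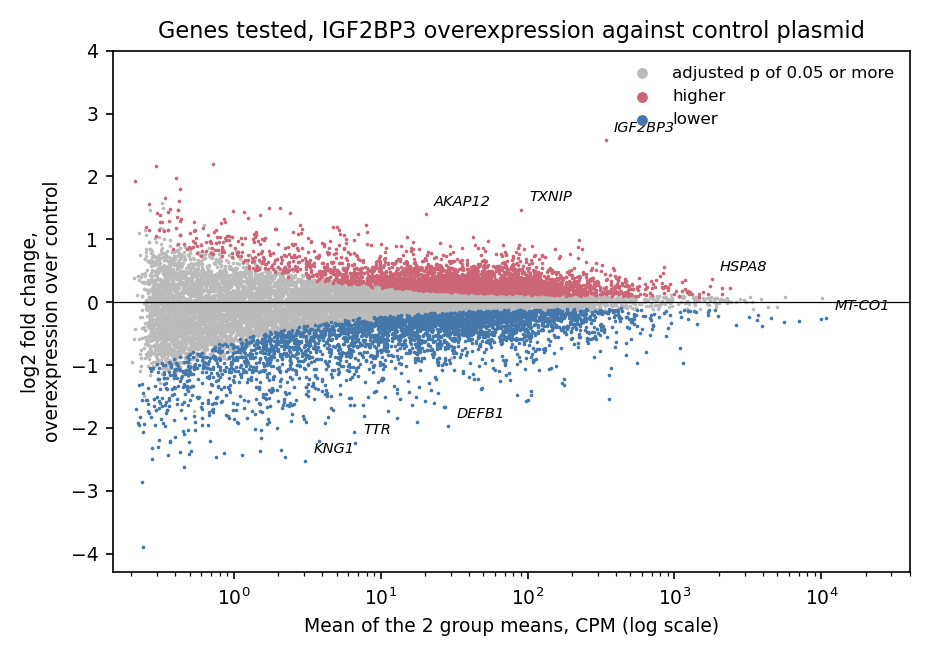
Log2 fold change (overexpression over control) against mean CPM (log axis) for the 17747 genes tested. Coloured points are the 3288 genes higher and 3410 lower at adjusted p under 0.05, and falls reach further from 0 than rises, with 512 falls and 84 rises of 2-fold or more.

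Among genes past the threshold with no overlap between the groups and at least 5 CPM in the higher group, the largest rises after IGF2BP3 were in TXNIP, AKAP12, FOSL1, HDAC9, LYPD1, SOCS2-AS1 and TLE3, with log2 fold changes from 1.47 down to 1.11. TXNIP, a thioredoxin-binding protein that responds to glucose, rose from 47.7 ± 4.31 to 132 ± 15.96 CPM (log2 fold change 1.47 ± 0.09, edgeR adjusted p = 7.402e-07). The kinase-anchoring protein gene AKAP12 rose from 11.1 ± 0.802 to 29.3 ± 5.83 CPM (1.40 ± 0.12), and FOSL1, a subunit of the transcription factor AP-1, from 4.73 ± 0.587 to 11.1 ± 2.12 CPM (1.23 ± 0.14). The histone deacetylase gene HDAC9 rose from 3.05 ± 0.602 to 6.99 ± 1.22 CPM and the corepressor gene TLE3 from 5.13 ± 0.232 to 11.1 ± 1.76 CPM (1.11 ± 0.12). SOCS2-AS1 (1.16 ± 0.12) is antisense to SOCS2 and is uncertain, because the strand setting of the counting is not given in the sources used here. SOCS2 itself, looked up after the values were seen, had a log2 fold change of 0.89 (adjusted p = 1.153e-05).

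Under the same limits the largest falls were in KNG1, TTR, ATOH8, SERPIND1, DEFB1, TMPRSS6, LGALS14 and MTTP. KNG1, which encodes kininogen, a plasma protein made in liver, fell 5.78-fold from 5.22 ± 0.454 to 0.907 ± 0.417 CPM (log2 fold change −2.53 ± 0.23, edgeR adjusted p = 9.123e-06). TTR, the carrier of thyroid hormone and retinol-binding protein in plasma, fell from 10.99 ± 1.25 to 2.35 ± 1.12 CPM (−2.24 ± 0.22). The transcription factor gene ATOH8 had a log2 fold change of −2.20 ± 0.18 and SERPIND1, which encodes the thrombin inhibitor heparin cofactor II, −2.07 ± 0.16. DEFB1, an epithelial antimicrobial peptide gene, fell from 46.0 ± 8.20 to 11.7 ± 2.84 CPM (−1.97 ± 0.16). TMPRSS6, a liver protease that acts on iron regulation, had −1.93 ± 0.18, the galectin gene LGALS14, whose relatives are near-identical and make it uncertain, −1.91 ± 0.19, and MTTP, which loads lipid onto apolipoprotein B, −1.84 ± 0.15. By CPM, the largest rises beside IGF2BP3 were HSPA8 (1562 to 2013 CPM), ENO1 (2203 to 2562 CPM) and NPM1 (1937 to 2271 CPM). The largest falls by CPM were the mitochondrial MT-CO1, MT-ND4, MT-CO2 and MT-CO3.

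**Figure D3:**
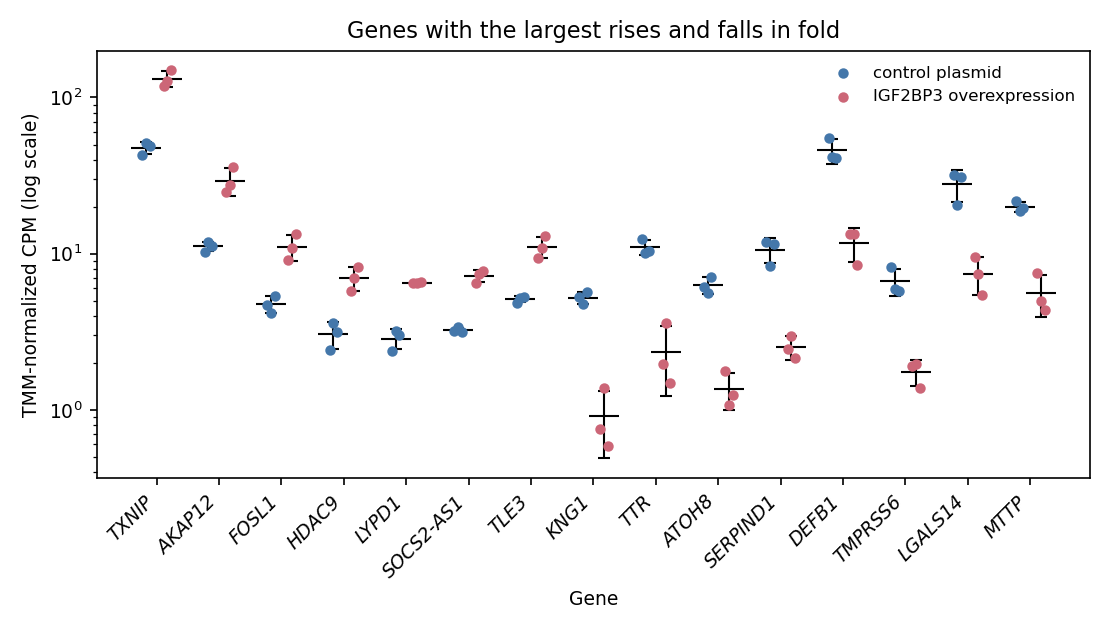
TMM-normalized CPM (log axis) of the 7 genes with the largest rises after IGF2BP3 and the 8 with the largest falls, among genes past the threshold with at least 5 CPM in the higher group and no overlap. Each point is a library and bars are the mean ± SD of 3 libraries; TXNIP lies at a mean of 47.7 CPM in controls and 132 CPM with overexpression, and KNG1 at 5.22 and 0.907 CPM.

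Camera called 15 of the 39 lists tested, 5 up and 10 down. With a correlation estimated from these 6 libraries it called 0 lists, 5 lists having an unadjusted p under 0.05, while fry called 25 lists, including these 15 in the same direction. The other 10 were the IGF2BP family, immediate-early genes, NF-kappaB targets, apoptosis regulators, TGF-beta targets, WNT targets, the insulin-like growth factor axis, NRF2 targets, matrix proteases and mesenchymal transition. Counts adjusted over the list alone stand beside those over all genes tested where they differ.

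**Figure D4:**
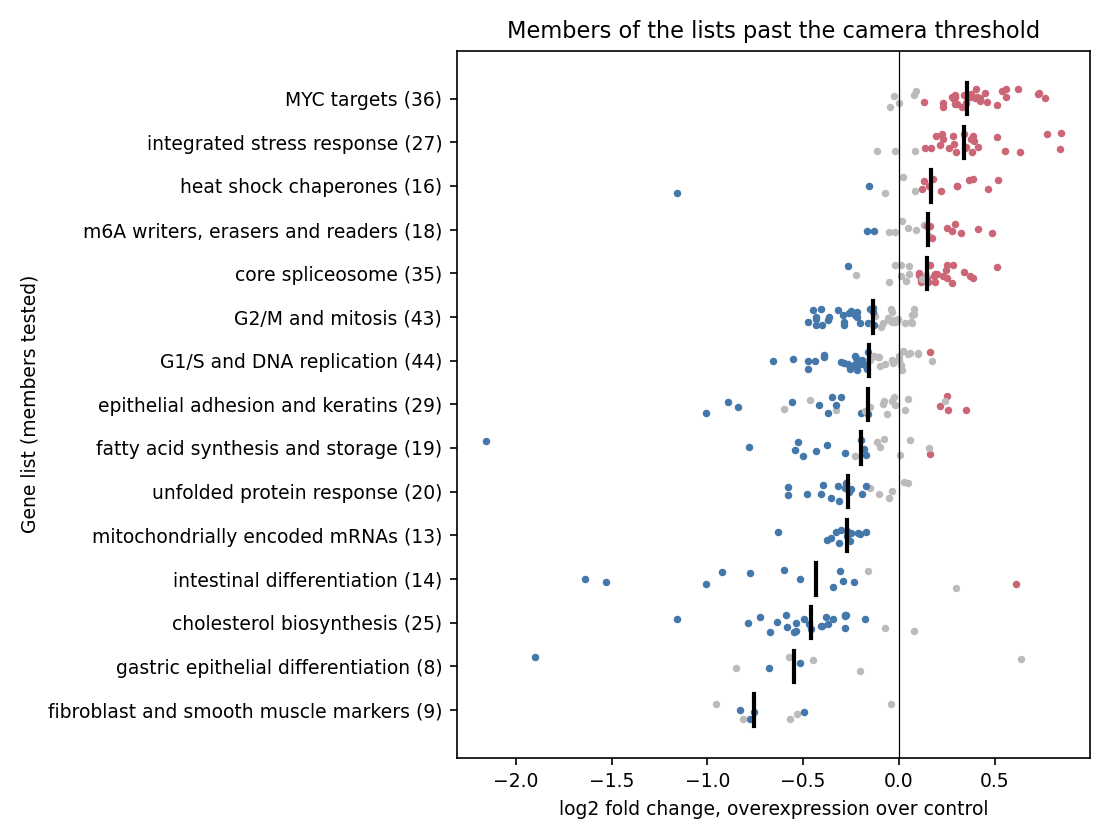
Log2 fold change (overexpression over control) of each tested member of the 15 lists that camera called, with the number of members tested in parentheses. Red and blue points passed adjusted p under 0.05 as higher and lower, grey points did not, and black bars are medians, from 0.36 for MYC targets to −0.76 for fibroblast and smooth muscle markers.

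MYC targets, genes of ribosome biogenesis and growth that MYC is known to activate, rose as a list. Of 36 members 31 rose, 0 fell and 5 did not pass, with a median log2 fold change of 0.36 (camera adjusted p = 1.791e-11; adjusted p = 0.28 with an estimated correlation). NOP2, an rRNA methyltransferase, rose from 145 ± 8.01 to 246 ± 15.7 CPM (0.76 ± 0.06), RRP12, a ribosome assembly factor, from 82.6 ± 3.72 to 137 ± 6.92 CPM, NOP16 from 92.7 ± 0.843 to 136 ± 7.04 CPM and the pseudouridine synthase gene DKC1 from 168 ± 5.58 to 244 ± 15.9 CPM. MYC itself, fixed among the immediate-early genes, rose from 67.5 ± 2.01 to 121 ± 9.19 CPM (0.84 ± 0.06, edgeR adjusted p = 2.142e-06).

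The integrated stress response list, genes induced through ATF4 when translation initiation is limited, also rose. Of 27 members 24 rose and 0 fell (24 and 1 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 5.784e-08; adjusted p = 0.39 with an estimated correlation). PPP1R15A, a phosphatase subunit that acts on eIF2, rose from 167 ± 7.14 to 300.2 ± 22.8 CPM (0.85 ± 0.06), ATF3 from 110.2 ± 10.4 to 197 ± 7.67 CPM, ATF4 from 679 ± 15.1 to 904 ± 4.04 CPM and the amino acid transporter subunit SLC3A2 from 497 ± 11.7 to 646 ± 13.9 CPM. Heat shock chaperones rose for 11 of 16 members (median 0.17, camera adjusted p = 0.012; adjusted p = 0.42 with an estimated correlation), among them HSPA8 (0.37 ± 0.03), HSPH1 (0.39 ± 0.06), HSPD1 (0.30 ± 0.05) and DNAJA1 (0.22 ± 0.04). BAG3 (−0.16) and the small heat shock protein gene CRYAB (−1.16), named after their values were seen, fell. The unfolded protein response of the endoplasmic reticulum went the other way, with 14 of 20 members lower, 0 higher and a median of −0.27 (camera adjusted p = 4.370e-05; adjusted p = 0.23 with an estimated correlation). The endoplasmic reticulum chaperone genes PDIA4 (235 ± 6.81 to 157 ± 5.14 CPM), HSP90B1 (357 ± 7.72 to 271 ± 1.36 CPM) and CALR (1036 to 783 CPM) fell. So did HERPUD1, a factor of protein degradation there (103 ± 3.04 to 68.9 ± 2.79 CPM).

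In the core spliceosome list 23 of 35 members rose and 1 fell (25 and 1 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 3.657e-05; adjusted p = 0.23 with an estimated correlation). PRPF3 (0.51 ± 0.06), PRPF4 (0.37 ± 0.05), PLRG1 (0.34 ± 0.05) and PRPF19 (0.25 ± 0.04) rose. SNRNP70 (−0.27), named after its value was seen, fell. Of 18 m6A writers, erasers and readers 9 rose and 2 fell, with a median of 0.15 (camera adjusted p = 0.039; adjusted p = 0.47 with an estimated correlation). The reader genes YTHDF2 (0.41 ± 0.05) and YTHDC1 (0.32 ± 0.06) and the writer-complex genes CBLL1 (0.49 ± 0.07) and RBM15 (0.25 ± 0.07) rose. The methyltransferase gene METTL3 (−0.17) and HNRNPA2B1 (−0.13), both named after their values were seen, fell. The m6A list lost its call without control replicate 1 (adjusted p = 0.055) and without overexpression replicate 3 (median 0.10, adjusted p = 0.056), without both (0.079), under 2 of the other filters and scalings and after removal of the GC trend. RBM15 lost its call without control replicate 3 or without overexpression replicate 1 (adjusted p = 0.055 and 0.060).

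In the cholesterol biosynthesis list 23 of 25 members fell, 0 rose and the median was −0.46 (camera adjusted p = 2.652e-10; adjusted p = 0.32 with an estimated correlation). The enzyme gene MSMO1 (140 ± 3.12 to 89.96 ± 4.09 CPM) and the sterol sensor gene INSIG1 (68.5 ± 0.460 to 43.0 ± 2.22 CPM) fell. In the list of fatty acid synthesis and storage 11 of 19 members fell and 1 rose (11 and 2 adjusted over the list alone), with a median of −0.20 (camera adjusted p = 0.0012; adjusted p = 0.23 with an estimated correlation). The desaturase genes SCD (1042 to 715 CPM), FADS2 (395 ± 16.8 to 230 ± 17.7 CPM) and FADS1 (178 ± 10.6 to 124 ± 6.90 CPM) fell. So did the acyltransferase gene GPAM at a low level (2.49 ± 0.193 to 0.553 ± 0.079 CPM). FADS1 lies within FADS2 on the opposite strand. Both are uncertain, because the strand setting of the counting is not given in the sources used here. ELOVL5 (0.16), named after its value was seen, rose.

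All 13 mitochondrially encoded mRNAs fell, with a median of −0.27 (camera adjusted p = 1.902e-05; adjusted p = 0.39 with an estimated correlation). MT-ND5 fell from 2951 to 2305 CPM, MT-ND6 from 487 ± 31.0 to 314 ± 26.2 CPM, MT-ATP6 had a log2 fold change of −0.38 ± 0.04 and MT-ND4 −0.27 ± 0.03. The mitochondrial genome took 6.30 ± 0.213% of counts in controls and 5.198 ± 0.143% with overexpression, with no overlap (exact permutation p = 0.1, the smallest possible with n = 3). The nuclear-encoded respiratory chain list did not pass (6 higher and 7 lower of 52, 6 and 6 adjusted over the list alone, camera adjusted p = 0.79), with NDUFC2 at −0.42 ± 0.06 and NDUFA9 at 0.31 ± 0.05.

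In the list of G1/S and DNA replication 22 of 44 members fell and 1 rose (25 and 2 adjusted over the list alone), with a median of −0.16 (camera adjusted p = 6.970e-04; adjusted p = 0.32 with an estimated correlation). The replicative helicase subunit gene MCM3 (424 ± 2.49 to 324 ± 10.2 CPM), the DNA ligase gene LIG1 (85.9 ± 3.20 to 58.5 ± 3.28 CPM), E2F1 (127 ± 1.60 to 91.4 ± 4.87 CPM) and the thymidine kinase gene TK1 (108 ± 5.23 to 68.3 ± 7.63 CPM) fell. RPA2 (0.16), named after its value was seen, rose. In the list of G2/M and mitosis 24 of 43 members fell and 0 rose, with a median of −0.14 (camera adjusted p = 7.257e-05; adjusted p = 0.33 with an estimated correlation). TOP2A (−0.43 ± 0.04), KIF20A (−0.43 ± 0.05), CCNB2 (−0.43 ± 0.06) and PTTG1 (−0.48 ± 0.06) fell.

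Of 14 intestinal differentiation genes 11 fell and 1 rose, with a median of −0.43 (camera adjusted p = 1.324e-04; adjusted p = 0.33 with an estimated correlation). The apolipoprotein gene APOB fell from 93.8 ± 4.44 to 49.6 ± 2.23 CPM, the fatty acid-binding protein gene FABP1 from 11.4 ± 1.95 to 3.67 ± 0.621 CPM, VIL1, a microvillus protein gene, from 431 ± 8.23 to 352 ± 4.31 CPM and APOA1 from 2.42 ± 0.080 to 0.836 ± 0.160 CPM. APOB, APOA1 and FABP1 are also expressed in liver cells. Of 43 hepatic secretory genes, a list written after values were seen that includes APOA1 and APOB, 40 fell (median −1.02). The mucin gene MUC13 (0.61), named after its value was seen, rose. In the list of epithelial adhesion and keratins 11 of 29 members fell and 4 rose (13 and 4 adjusted over the list alone), with a median of −0.16 (camera adjusted p = 0.023; adjusted p = 0.32 with an estimated correlation). The call ended when the GC trend was removed (adjusted p = 0.077). E-cadherin, encoded by CDH1, fell from 125 ± 6.04 to 84.7 ± 1.962 CPM, MUC1 from 22.4 ± 0.562 to 12.1 ± 1.95 CPM, ESRP1 from 99.98 ± 2.77 to 75.0 ± 1.68 CPM and plakoglobin, encoded by JUP, from 240.1 ± 8.61 to 189 ± 11.3 CPM. The members that rose, named after their values were seen, were TJP1 (0.25), DSG2 (0.21), KRT7 (0.35) and OCLN (0.26). Of the 28 genes in the list of gastric epithelial differentiation only 8 could be tested, and of these 3 fell and 0 rose, with a median of −0.55 (camera adjusted p = 0.033; adjusted p = 0.42 with an estimated correlation). They were PGC, the pepsinogen C gene (3.87 ± 0.504 to 1.04 ± 0.224 CPM), the secretory cell transcription factor gene BHLHA15 (31.2 ± 1.82 to 19.5 ± 1.67 CPM) and the trefoil factor gene TFF3 (3.10 ± 0.360 to 2.17 ± 0.262 CPM). The gastric list lost its call without control replicate 1 (adjusted p = 0.051), without that library and overexpression replicate 3 (0.053) and under upper quartile scaling (adjusted p = 0.054). TFF3 lost its call without control replicate 3 (adjusted p = 0.098), without overexpression replicate 2 (0.070) or 3 (0.077) and with DESeq2 (0.060).

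Among markers of other cell types, 4 of 9 fibroblast and smooth muscle markers fell (5 adjusted over the list alone) and 0 rose, with a median of −0.76 (camera adjusted p = 0.0036; adjusted p = 0.32 with an estimated correlation). Without control replicate 1 and overexpression replicate 3 together the median was −0.43 (adjusted p = 0.031). The members that fell were the matrix genes LUM (164 ± 7.54 to 97.2 ± 6.08 CPM), COL1A2 (29.4 ± 1.75 to 16.5 ± 1.05 CPM), COL1A1 (18.7 ± 1.02 to 13.3 ± 0.620 CPM) and COL3A1 (1.05 ± 0.107 to 0.610 ± 0.089 CPM). COL3A1 lost its call without control replicate 2 (adjusted p = 0.065) or 3 (0.083), without overexpression replicate 1 (0.086) and with DESeq2 (0.11). With limma on log2 FPKM it lost its call at pseudocounts of 1 (adjusted p = 0.072) and, narrowly, 0.1 (0.05001). Leukocyte markers did not pass as a list (1 higher and 2 lower of 4 tested members, camera adjusted p = 0.53), with CD14 at 69.0 ± 3.26 and 26.5 ± 5.28 CPM (−1.38 ± 0.11) and LYZ at 11.2 ± 0.791 and 7.47 ± 0.814 CPM (−0.58 ± 0.10), both past the gene threshold. The list of mesenchymal transition did not pass (7 higher and 9 lower of 24, 8 and 10 adjusted over the list alone, camera adjusted p = 0.63), while its members FN1 (1367 to 825 CPM) and COL5A2 (272 ± 3.16 to 166 ± 7.94 CPM) fell.

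Of mRNAs reported elsewhere as bound or stabilised by IGF2BP3, 11 of 35 rose and 8 fell (13 and 9 adjusted over the list alone), with a median of 0.08 and no call for the list (camera adjusted p = 0.31). MYC rose and IGF2 fell, the latter from 604 ± 36.2 to 336 ± 43.4 CPM (−0.85 ± 0.08, edgeR adjusted p = 9.963e-06). In the insulin-like growth factor axis 4 of 22 members rose and 6 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.31), with IGF2 and IGFBP3 (−0.52 ± 0.05) lower. Immediate-early genes just missed the threshold, with 9 of 20 higher and 5 lower (10 and 5 adjusted over the list alone, median 0.21, camera adjusted p = 0.065), and passed it under upper quartile scaling (adjusted p = 0.034), with no filter (0.033), without control replicate 3 (0.039) and with fry (0.0023). With an estimated correlation camera gave that list an adjusted p of 0.39. JUN rose from 84.2 ± 3.20 to 142 ± 7.88 CPM. The list of cytosolic ribosomal proteins, 11 of 65 higher and 1 lower, did not pass either (median 0.05, camera adjusted p = 0.096; 7 higher and 0 lower adjusted over the list alone). It passed without overexpression replicate 3 (adjusted p = 1.429e-04), without that library and control replicate 1 (1.026e-04), with no filter (0.0050) and after removal of the GC trend (adjusted p = 0.0069). It did not pass with fry (adjusted p = 0.40) or with camera and an estimated correlation (adjusted p = 0.78). RPL7 (0.17 ± 0.04) and RPL19 (0.17 ± 0.04) were higher and, like other ribosomal protein genes, have many processed pseudogenes, which makes their counts uncertain.

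Signalling and stress lists held members that moved both ways. TGF-beta targets had 3 higher and 9 lower of 18 (4 and 9 adjusted over the list alone, camera adjusted p = 0.12; median −0.22), with CCN2 (576 ± 13.8 to 366 ± 29.01 CPM) and TGFBI (192 ± 3.95 to 109.9 ± 11.8 CPM) lower. The list passed without control replicate 1 and overexpression replicate 3 together (median −0.33, adjusted p = 0.031) and with fry (adjusted p = 0.0050). With an estimated correlation camera gave it an adjusted p of 0.47. YAP/TAZ targets, which also hold CCN2 and IGFBP3, had 9 higher and 5 lower of 26 (10 and 6 adjusted over the list alone, camera adjusted p = 0.27). WNT targets had 1 higher and 5 lower of 14 (2 and 6 adjusted over the list alone, camera adjusted p = 0.36), with DKK1 at −0.49 ± 0.05. NF-kappaB targets and inflammatory cytokines had 11 higher and 6 lower of 25 (camera adjusted p = 0.17), the chemokine gene CXCL1 falling (−1.14 ± 0.08) and BIRC3 rising (1.04 ± 0.10). Apoptosis regulators had 10 higher and 5 lower of 28 (camera adjusted p = 0.31), BCL2L1 falling (−0.49 ± 0.04). Hypoxia-responsive genes had 7 higher and 10 lower of 24 (camera adjusted p = 0.51), ADM (0.62 ± 0.04) and STC2 (0.77 ± 0.08) rising. Glycolysis had 6 higher and 10 lower of 23 (7 and 10 adjusted over the list alone, camera adjusted p = 0.53), PFKFB3 (−0.78 ± 0.07) and ALDOC (−0.65 ± 0.08) falling. NRF2 targets and metallothioneins had 7 higher and 12 lower of 25 (camera adjusted p = 0.51), NQO1 (−0.58 ± 0.04) and AKR1C1 (−0.76 ± 0.07) falling. AKR1C1 has near-identical relatives and is uncertain. Matrix proteases and inhibitors had 4 higher and 6 lower of 15 (camera adjusted p = 0.57), ADAMTS1 falling (−0.54 ± 0.04). Targets of p53 had 7 higher and 7 lower of 25 (camera adjusted p = 0.77; median −0.01 and mean 0.06), GADD45A (0.89 ± 0.08) and PLK2 (0.60 ± 0.06) rising.

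Interferon-stimulated genes had 5 higher and 12 lower of 33 and no call (camera adjusted p = 0.64); their median was 0.02 and their mean −0.09. LGALS3BP fell from 72.2 ± 1.50 to 46.6 ± 4.67 CPM. Of 7 tested interferons and nucleic acid sensors, TBK1 rose and MAVS fell (camera adjusted p = 0.86; the median was −0.07 where camera's direction was up). The MAVS value rested on control replicate 1: its log2 fold change was −0.40 with that library and −0.17 without it (adjusted p = 0.012). It kept its call there but lost it without any 1 of the overexpression libraries (adjusted p = 0.060 to 0.095) and with DESeq2 (0.16). MAVS also lost it with limma in all 3 settings on FPKM (adjusted p = 0.078 to 0.12). TBK1 (0.20 ± 0.06) lost its call without control replicate 1 (adjusted p = 0.052) or overexpression replicate 3 (0.054). With limma on log2 FPKM it lost its call at pseudocounts of 1 (adjusted p = 0.063) and 0.1 (0.057). MHC class I genes had 4 higher and 2 lower of 15 (camera adjusted p = 0.39), HLA-E (0.24 ± 0.05) and ERAP2 (0.73 ± 0.17) rising, with HLA-E uncertain for its similar relatives. SR proteins and other splicing regulators had 8 higher and 6 lower of 30 (camera adjusted p = 0.42), with RBM39 at 0.34 ± 0.05. The hnRNP proteins had 5 higher and 3 lower of 20 (camera adjusted p = 0.27), with HNRNPU at 0.24 ± 0.04 and HNRNPK at 0.22 ± 0.04. Replication-dependent histones, whose mRNAs mostly lack a polyA tail and are poorly caught by this capture, had 2 higher and 3 lower of 23 (2 and 1 adjusted over the list alone; camera adjusted p = 0.21). H2BC12 was at −0.25 ± 0.07, and lost its call at 0.01 after removal of the GC trend (adjusted p = 0.93). Across 11099 genes with a mean of at least 5 CPM, log2 fold change fell with GC content (Spearman rho −0.25, across genes, which are not independent replicates).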

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

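The tests of GC content and transcript length, of a fold of 1.5 by glmTreat and without control replicate 1 and overexpression replicate 3 together were chosen after seeing the data; the others were planned. IGF2BP3 kept its direction and its side of the threshold in all 20 alternatives run, with log2 fold changes from 2.42 to 2.67 and adjusted p of 1.016e-04 or less. The 6698 genes called became 1674 with a fold of 1.5 or more, 596 with a fold of 2 or more, 4293 at an adjusted p under 0.01 and 367 when tested against a fold of 1.5, each a stricter limit by construction. Leaving out 1 library gave 5530 to 6107 genes, and at least 79.3% of the 6698 were called again in the same direction. DESeq2 called 5943 and limma-voom 6678. Leaving out the pair of libraries that lay farthest out gave 6936 genes and removing the GC and length trend 7470, of which 4216 were higher and 3254 lower, a balance turned from 3288 and 3410. Under upper quartile scaling 60.5% of calls were lower, against 50.9% under TMM, and the median of all genes moved from −0.01 to −0.05. The 15 lists called became 0 with an estimated correlation and 25 with fry. Fry asks another question than camera, and with 3 libraries per group the correlation estimate has few degrees of freedom; the cause was not tested further. Leaving out 1 library gave 13 to 16 lists.

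The labels do not say whether the replicate numbers pair the libraries. Deviations from the group means correlated by 0.23, −0.32 and 0.22 between libraries with the same number, which does not decide it. With the replicate block 6848 genes and 15 lists were called.

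Of 2391 values of 120 named genes under alternatives, 2360 kept direction and side of the threshold, 23 values of 5 genes (COL3A1, MAVS, RBM15, TBK1 and TFF3) missed it, and 8 of 2 genes changed sign, where H2BC12 also missed it. IGF2BP2, not called in any setting, was at 0.0079 with no filter, 0.030 and 0.036 on log2 FPKM with pseudocounts of 1 and 0.1, 0.030 on FPKM with a mean of at least 1, and from −0.053 to 0.0091 without 1 library. H2BC12 was at 0.0085 after removal of the GC and length trend and lost its call (adjusted p = 0.93), and the cause was not tested. Of 663 list values, 610 kept direction and call, 25 lost a call, 18 gained one and 10 changed direction, all of 4 lists never called in the settings where they turned. The median of the nuclear-encoded respiratory chain was −0.035 under upper quartile scaling, −0.0013 with the filter of 1 CPM, −0.0093 to 0.040 without 1 library and 0.048 without control replicate 1 and overexpression replicate 3 together. Matrix proteases and inhibitors had −0.029 with no filter, and SR proteins and other splicing regulators −0.0032 after removal of the GC and length trend. Interferons and nucleic acid sensors had −0.15 to −0.00083 without 1 library and 0.0013 without control replicate 1 and overexpression replicate 3 together. Without those libraries the median of the fibroblast and smooth muscle markers was −0.43, still past the threshold (adjusted p = 0.031). Of genes under a mean of 10 CPM 22.4% were called, and of the others 50.9%; recovery by level was not tested.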

Other observations

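The lists below were written after the genes with the largest changes had been seen, so they are not independent evidence, and the test of a single dilution factor, that of TMM scaling and those on GC content were chosen after results had been seen. The libraries, labelled AGS, held abundant transcripts of plasma proteins that are otherwise made in liver, with albumin at 1512 CPM in controls, while 8 of 28 gastric differentiation genes were high enough to be tested. Whether the cells match the record of that line was not tested here and stays in doubt. The plasma protein genes fell together. Of 43 tested hepatic secretory genes 40 fell and 0 rose, with a median log2 fold change of −1.02 (camera adjusted p = 3.430e-20 over these 6 lists; adjusted p = 0.097 with an estimated correlation), and together they took 0.676 to 0.721% of counts in control libraries and 0.381 to 0.432% with overexpression. The albumin gene ALB fell to 770.1 CPM, alpha-fetoprotein, AFP, from 531 ± 28.0 to 182 ± 22.8 CPM, complement C3 from 495 ± 17.1 to 239 ± 23.7 CPM and transferrin, TF, from 155 ± 11.4 to 55.7 ± 6.57 CPM. The fibrinogen genes FGB (−0.21), FGA (−0.38) and FGG (−0.38) fell less. Of 18 hepatic transcription factors 11 fell and 2 rose (median −0.26, and −0.16 after removal of the GC and length trend; camera adjusted p = 0.0030; adjusted p = 0.097 with an estimated correlation), with CEBPA at −1.05, FOXA1 at −0.71, HNF4A at −0.24 and, in the other direction, GATA6 at 0.70 and CEBPB at 0.29. APOA1 and APOB of the secretory genes, and 3 of the factors, among them CEBPB and HNF4A, were also in the lists fixed earlier.

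Of 20 cytosolic aminoacyl-tRNA synthetases 15 rose and 1, QARS1 (−0.39), fell (median 0.27, camera adjusted p = 2.469e-06; adjusted p = 0.099 with an estimated correlation). AARS1, GARS1 and WARS1 among these, and EIF4A1 among the next, were also in the lists fixed earlier. Of 33 translation initiation factors 25 rose and 0 fell (median 0.21, camera adjusted p = 1.931e-07; adjusted p = 0.097 with an estimated correlation), among them EIF6 (0.51) and EIF2S1 (0.47). Among 176 families of genes that share a symbol prefix, camera called 26 up and 7 down, and none with an estimated correlation. Mitochondrial ribosomal proteins rose for 22 of 30 MRPS and 28 of 51 MRPL genes, and all 10 UTP genes of small ribosomal subunit assembly rose. Collagens fell for 18 of 28 genes with 2 higher (median −0.54), ABCC transporters for 8 of 11 and semaphorins for 11 of 19 with 2 higher.

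The fall of the hepatic secretory genes was weighed first: a loss of cells that were the only source of these transcripts would lower all of them by 1 factor. Among 31 members with at least 10 CPM in controls the log2 fold changes had an interquartile range of 0.42 and differed beyond their errors (Cochran's Q 980), which argues against a single factor. It does not exclude a smaller share of liver-like cells where the other cells express some of these genes too, and that stays open. The median stayed at −1.02 after removal of the GC and length trend and at −0.998 without control replicate 1, against either as the whole cause. A response of the cells to IGF2BP3 overexpression is a candidate explanation, as a hypothesis, and a difference in how the groups were cultured or transfected, which no label describes, stays open.

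The excess of falls over rises at a fold of 1.5 or more, 1268 against 406, was weighed next. Falls divided by rises stayed at 2.24 after removal of the GC and length trend, at 1.99 to 2.21 in the 3 settings on the authors' FPKM, whose totals differ from the count sums, and at 2.44 among the 9562 genes with a mean of at least 10 CPM. A GC trend or genes of low count alone would have brought these ratios to about 1, so the tables argue against either as the whole cause. The GC correction and the FPKM did lower the ratio from 3.12. A wrong scale adds 1 constant to every gene, and about the median of all genes 2.77 times as many lay 1.5-fold or more below as above. TMM had already put that median at −0.01, so this value takes the median gene as unchanged and cannot decide on the scaling. Falls divided by rises were 4.54 under upper quartile scaling and 3.08 with library totals only. A part of TMM scaling in the excess stays open. Controls had more genes detected, 26212 to 26973 against 25736 to 25969 with overexpression (exact permutation p = 0.1, the smallest possible). The gene counts' share of the totals behind the FPKM differed by group too. Whether either bears on the excess was not tested. Handling of the groups before sequencing stays open, and an effect of IGF2BP3 may remain as a hypothesis.

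The snoRNA host long noncoding RNAs rose for 14 of 25 genes with 0 lower and a median of 0.32 (camera adjusted p = 1.714e-06; adjusted p = 0.052 with an estimated correlation). ZFAS1 rose from 151 ± 8.64 to 300 ± 9.33 CPM, GAS5 from 155 ± 5.10 to 286 ± 12.5 CPM and SNHG15 from 47.3 ± 1.87 to 89.0 ± 5.10 CPM. The median was 0.35 after removal of the GC and length trend and 0.30 without control replicate 1, against either as the whole cause. Spliced transcripts of several such hosts are known to be degraded by nonsense-mediated decay, and 14 decay factors and coding targets, whose own mRNAs that pathway limits, had a median of 0.34 with 12 higher and 0 lower (camera adjusted p = 7.611e-07; adjusted p = 0.097 with an estimated correlation), among them UPF3B (0.80), SMG9 (0.67) and UPF1 (0.46). This is consistent with lower decay in the overexpression libraries, as a hypothesis, but GADD45A and GADD45B are also stress genes, and higher transcription of these genes was not tested and would need RNA half-lives, not used here, to be told from it.

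Other splits of the 6 libraries were set beside the counts. The real grouping gave 6698 genes, and the highest of the other 9 splits gave 0 by edgeR, with 122 to 359 genes at an unadjusted p under 0.05. The real grouping gave 15 lists by camera, against 3 to 8 in the other splits. Camera at its preset correlation thus called lists in splits where edgeR called 0 genes. In both cases only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Every other split puts libraries of both groups on each side, so the group difference enters its spread and holds down the genes called. The 0 genes therefore do not show how many calls arise without a difference. The 3 to 8 lists do not show it either, since no such split balances the groups. How many of the 15 list calls would arise without a difference is therefore not known.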
